A study of Rattus norvegicus with 18 samples.

How the data were processed

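RNA of rat H9c2 cells was measured in 18 samples: control, bufalin and periplocin, each with 3 IP and 3 input libraries, per the labels. Libraries came from a stranded mRNA kit with unique molecular identifiers. Per the submitters' processing notes, HISAT2, StringTie and DESeq were used with the rn6 build; their versions are not given in the sources used here. Samples were grouped by compound and library kind as labelled. The deposited files hold 1 value per gene or peak and comparison, so depth and spread of single libraries were not analysed here, and precision is given by the authors' standard errors.

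The signal in the expression tables is the mean over libraries of counts that the authors divided by size factors, as DESeq2 defines this column in the deposited tables. The log2 fold changes and their standard errors are the authors' DESeq2 estimates, per the file headers. The test score was read as the authors' Wald statistic, the fold change divided by its standard error, apart from its sign in the periplocin table. Likewise the p-values were read as Wald p-values, and the adjusted p-values as Benjamini-Hochberg with a filter on mean count. The column names alone do not state these methods. Whether these tables were made from input or IP libraries is not stated. The fold enrichment of a peak was read as the ratio of IP over input, which its column name does not state. The log10 values in the peak lists are logarithms of the p and FDR of enrichment and of its change, per the file headers. The caller is not given in the sources used here.

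The direction of the RNA values was worked out from both tables. Control means computed from the mean and the fold change coincided between the tables, within 1% in 10681 of 10682 genes after an offset of 0.05 (log2), only with both changes read as treated over control. In the periplocin table the sign of the Wald score is opposite to that of the fold change in all 12913 genes, and in the bufalin table the signs match in all 12881, so signs were taken from the fold changes. The direction of the m6A change is not stated and was read as treated over control. An adjusted p was deposited for 3321 genes with bufalin and 12445 with periplocin, and 5 and 7 genes with a mean above 0 had no p.

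Expression calls are the authors' adjusted p under 0.05. The plan for bufalin against periplocin was a fit on counts per sample; with comparisons only, it became an approximate Wald test of the difference of the log2 fold changes over 10682 genes with a mean of at least 10. From each standard error the spread between libraries beyond counting noise was worked out, taken as equal in the treated and control groups of a table and as 0 where negative. The standard error of the difference joins this spread and the counting noise of the 2 treated groups, and the controls cancel. An upper limit of the standard error ignores the shared controls. The test was checked on simulated data with 10682 genes, where it recovered 22%, 68%, 80% and 96% of 50 genes changed by 0.25, 0.5, 1 and 2 on the log2 scale. In these data the spread of a gene was known and equal in all groups, so the rates are a best case. For a fitted control mean under 1, folds were computed against a floor of 3 counts per library.

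Overlaps used Fisher's exact test, with 100 simulations of unchanged groups against shared controls. For 26 gene lists with 598 genes, fixed before the data were examined, the median change was ranked among 10000 random lists of equal size matched in 20 bins of mean expression, adjusted by Benjamini-Hochberg over lists with at least 3 measured genes. The smallest p this gives is 0.000200. Peaks with an FDR of the change under 0.05 were counted, and directions tested with exact binomial tests. Peaks overlapped when sharing 1 base on the same chromosome and strand. Mean peak change per gene was correlated with the RNA change, with 100000 permutations.

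Named genes followed a rule: per compound, the 8 largest rises and 8 largest falls among called genes with a mean at or above the median and a proper symbol; up to 4 called members per list; all measured pump and m6A genes; and the called peaks with the largest changes. Single genes that the rule takes but the text does not name are not reported here, and all counts and tests include them. Alternatives covered thresholds, count filters, list matching, peak length, overlap and the peak taken per gene. A RefSeq table of assembly GRCr8 was used only for names, gene lengths and neighbours, and matched 98.0% of the gene names; its coordinates differ from rn6 and were not used. Peak features along transcripts and sequence motifs were left out, because they need the rn6 genome and annotation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.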

Results

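The data came from H9c2, a myoblast line of rat heart, grown as control cells or treated with bufalin or periplocin. Both compounds are cardiotonic steroids, plant or toad poisons that block the sodium and potassium pump of the cell membrane. Bufalin is a bufadienolide without a sugar, and periplocin is a cardenolide with sugars attached. The series asked whether N6-methyladenosine (m6A), a methyl mark on mRNA, takes part in their toxicity to heart cells. RNA was read by methylated RNA immunoprecipitation sequencing (MeRIP-seq), in which an m6A antibody pulls down modified fragments (IP) and an input library gives the RNA before pull-down. The 18 samples formed 6 groups of 3, an IP and an input group for each of 3 conditions. Dose and time are not in the labels, so values of the compounds stand side by side without a known match of dose. The labels do not say whether replicates were separate cultures. The authors' p-values and those between the compounds thus measure the spread between these samples only. The p-values of lists, directions, overlaps and correlations were computed across genes or peaks and measure no spread between samples.

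The values analysed were the authors' comparisons with control, with 1 value per gene or peak and none per library. Each expression table listed 17455 genes, of which 12876 had a p-value for bufalin and 12906 for periplocin. Genes with a p-value had a median mean of 663 normalized counts in the bufalin table and 640 in the periplocin table, and the depth of single libraries was not analysed here. Among genes with a mean of at least 10, the median standard error of a log2 fold change was 0.11 in both tables. Intervals given with folds are 95% Wald intervals from the authors' standard errors.

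With bufalin, RNA levels of 10 genes passed an adjusted p of 0.05 against control, 6 higher and 4 lower, and every change was under 2-fold. H19, an imprinted long noncoding RNA, was 1.43-fold higher (interval 1.34 to 1.52), and its log2 change in the authors' deposited table was 0.51 ± 0.05 (SE) with an adjusted p of 9.01e-23. Spp1, which encodes the secreted protein osteopontin, was 1.47-fold higher (interval 1.27 to 1.70). The transcripts of the growth factor Tgfb3 and of the matrix-associated protein Ccn2 fell to 0.811-fold (interval 0.738 to 0.890) and 0.824-fold (interval 0.754 to 0.900) of control.

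Further risers in the authors' deposited table included Myh1, a fast skeletal myosin heavy chain, at 0.47 ± 0.11 (SE, log2). Dnmt3a, a DNA methyltransferase, and Crebbp, a histone acetyltransferase, both stood at 0.29 ± 0.07 in the authors' deposited table. The fallers there were the calcium sensor Ncald at -0.33 ± 0.07, Tgfb3 at -0.30 ± 0.07, Ccn2 at -0.28 ± 0.07 and the chemokine Cxcl12 at -0.25 ± 0.05, from the authors' deposited table. Adjusted p-values of these genes and Spp1 ran from 0.000202 for Spp1 to 0.0130 for Myh1 in the authors' deposited table, by the Wald test of DESeq2 with Benjamini-Hochberg adjustment.

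An adjusted p was given for 3321 of the genes in the bufalin table, all with a mean normalized count of at least 2259. Over all genes with a p-value, 644 of 12876 had an unadjusted p under 0.05.

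With periplocin, 67 genes passed an adjusted p of 0.05, and 64 of them were higher than in control. The largest change at a moderate level of RNA was in Fosb, a subunit of the transcription factor AP-1, at 4.52-fold (interval 3.37 to 6.07). Other transcription factors of the rapid response to stimuli were higher too: Atf3 at 2.03-fold (interval 1.49 to 2.76), Myc at 1.82-fold (interval 1.55 to 2.14) and Fosl1 at 1.63-fold (interval 1.40 to 1.90). Ppp1r15a, a phosphatase subunit that reverses the translation block of the stress response, was 1.72-fold higher (interval 1.40 to 2.12). Only Steap2, Itga4 and Hspb1 were lower among the 67, at 0.758-fold, 0.832-fold and 0.868-fold of control.

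Among the largest rises in the authors' deposited table were Vof16 at 0.83 ± 0.15 (SE, log2), Edn1, the precursor of the peptide endothelin, at 0.68 ± 0.13, Ppp1r10, a nuclear regulator of protein phosphatase, at 0.65 ± 0.09, and Zfand2a, an arsenite-inducible gene, at 0.56 ± 0.11. Of p53 targets, Plk3 stood at 0.54 ± 0.13 and Mdm2, the ligase that degrades p53, at 0.36 ± 0.07 in the authors' deposited table. Thbs1, a matrix glycoprotein, rose by 0.23 ± 0.05 in the authors' deposited table. Falls there were -0.40 ± 0.08 for the metalloreductase Steap2, -0.27 ± 0.07 for the integrin chain Itga4 and -0.20 ± 0.05 for the small heat shock protein Hspb1, from the authors' deposited table. Rps9l1 stood at 0.59 ± 0.13 in the authors' deposited table, but it is by name a copy of Rps9. Its level is uncertain if both share reads, which was not measured. The adjusted p of Fosb was 1.49e-19 and that of Atf3 0.00263 in the authors' deposited table, by the same DESeq2 test.

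Of the 67 genes, 8 had a fitted control mean under 1 normalized count, so their folds were lower bounds, computed against a floor of 3 counts per library. Mboat7 was at least 21.3-fold higher, and Oprl1, Ccdc153, RT1-Bb, Lrrc19, LOC100909941, Rps6kl1 and Pcdhga8 were at least 5.80-fold, 5.69-fold, 5.55-fold, 4.89-fold, 4.54-fold, 4.39-fold and 4.29-fold higher (named after their values were seen). Mboat7 has a copy by name, Mboat7l1, so the level of Mboat7 is uncertain if both share reads, which was not measured either.

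**Figure D1:**
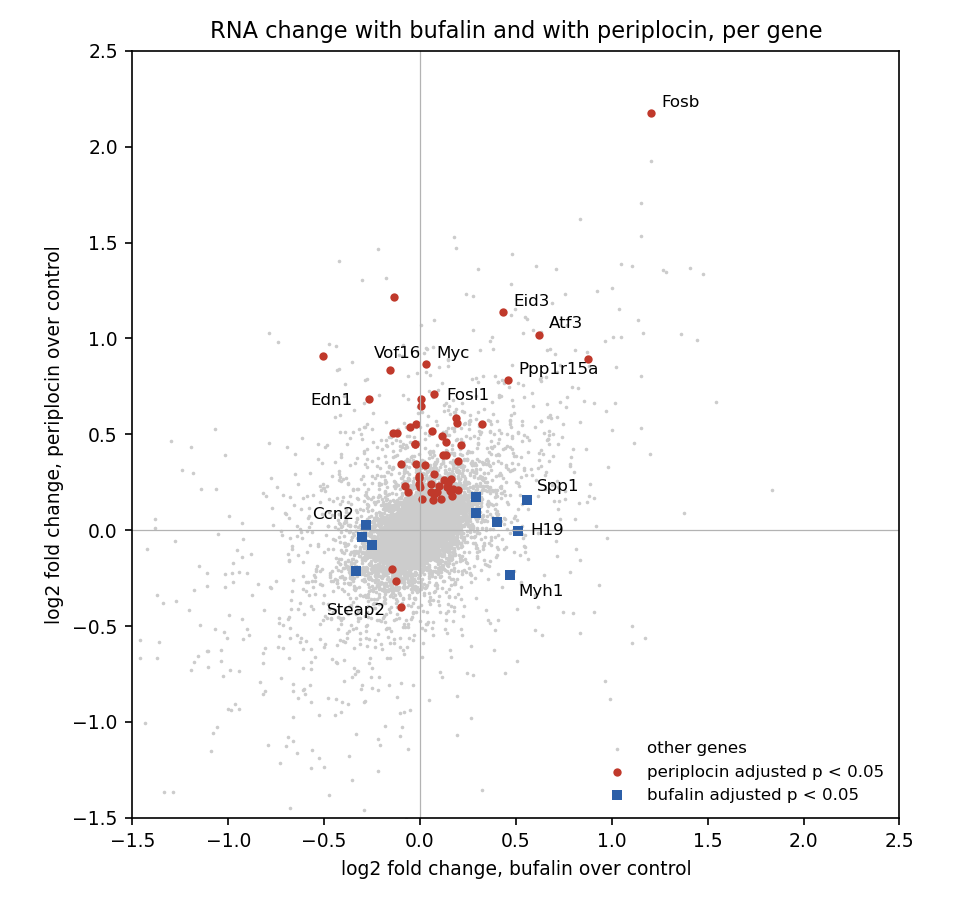
Log2 fold change over control with bufalin (horizontal axis) and with periplocin (vertical axis), 1 point per gene with a fitted control mean of at least 10, with 69 of 10667 genes outside the axes. Blue squares are the 10 genes past an adjusted p of 0.05 with bufalin and red circles the 59 drawn of those past it with periplocin, and Fosb stands apart at 1.20 and 2.18.

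The compounds were compared with each other through the control they share. Periplocin-treated cells held more RNA of Myc, Edn1, Vof16, Fosl1, Ppp1r10, Plk3 and Thbs1 than bufalin-treated cells, and bufalin-treated cells held more of H19 and Myh1. For Myc the bufalin minus periplocin difference was -0.84 ± 0.12 (SE, log2), for Edn1 -0.95 ± 0.15 and for Vof16 -0.99 ± 0.15. For Myh1 it was 0.70 ± 0.11 and for H19 0.52 ± 0.05. Tgfb3 and Ccn2 were lower with bufalin than with periplocin, with differences of -0.27 ± 0.06 and -0.30 ± 0.07.

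In all, 42 of 10682 genes with a mean of at least 10 passed an adjusted p of 0.05 in this comparison, 11 higher with bufalin and 31 higher with periplocin. Genes called against control by 1 compound did not always differ between them. Of the 10 bufalin genes 5 passed, and of the 60 periplocin genes tested 20 passed. For Fosb the difference was -0.97 with an interval of -1.57 to -0.37 and an adjusted p of 0.171, for Ppp1r15a -0.33 with -0.71 to 0.06, and for Mdm2 -0.16 with -0.45 to 0.13, so none of these 3 was shown to differ or to act alike. The test is an approximate Wald test rebuilt from the authors' standard errors, and in simulated data of this comparison over 10682 genes 16 of its 149 calls were false. Those data had a known spread equal in all groups, so the share of false calls may be higher in the real data. With an upper limit of the standard error that ignores the shared controls, 8 genes passed: H19, Myh1, Myc, Vof16, Edn1, Klf6, Dusp1 and Amotl2, the last 3 named after their values were seen.

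No gene passed an adjusted p of 0.05 with both compounds by the DESeq2 test of the authors. Among the 3321 genes with an adjusted p in both tables, the 6 bufalin risers and 33 periplocin risers shared 0 genes, where independent lists share 0.0596, and the 4 and 2 fallers shared 0, where independent lists share 0.00241 (one-sided Fisher's exact test, p = 1 for both directions). With so few genes expected, 0 shared genes carries no information on whether the compounds act alike. Fosb, Myc, Atf3 and Fosl1 had no adjusted p with bufalin and did not enter this test. At an unadjusted p under 0.05, 108 genes were higher with both compounds and 53 lower with both, against 15.6 and 5.58 for independent lists.

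Both comparisons used the same control libraries, which alone gives shared changes. Over 10682 genes with a mean of at least 10, 137 genes passed an unadjusted p of 0.05 with the same sign and 4 with opposite signs. In 100 simulations of unchanged groups against shared controls, the mean was 127 genes with the same sign and the highest 155, and 0.07 genes with opposite signs. The observed genes split into 91 higher and 46 lower with both compounds, and the simulated ones into 63.8 and 63.6. Over 8456 genes with a mean of at least 200, the fold changes of the compounds correlated at r = 0.455 across genes, and at 0.514 in the simulations. The covariance was 0.00690, within the simulated range of 0.00686 to 0.00891, whose mean was 0.00761. Genes are not independent replicates in these correlations.

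Gene lists fixed before the data were examined were set against random lists matched on expression. With periplocin, the 26 immediate early genes, which respond to stimuli within minutes to hours, had a median log2 change of 0.47, 24 of them were above 0, and 9 rose at an adjusted p of 0.05 (adjusted p of the list 0.00167). Those 9 were Fosb, Atf3, Myc, Fosl1, Klf6, Dusp1, Csrnp1, Klf4 and Fosl2, and 15 members passed when adjusted over the list alone. With bufalin the same list had a median of 0.00, with 13 members above and 13 below 0 (adjusted p of the list 0.981). Only 13 of the 26 members had an adjusted p with bufalin, and none of those 13 was called. With p re-adjusted over all genes that have one, 0 of the 26 passed with bufalin and the same 9 with periplocin. Fosb passed in the bufalin comparison when adjusted over the list alone, at 1.20 ± 0.38 (SE, log2) in the authors' deposited table. The median of the bufalin minus periplocin differences over the list was -0.38 (adjusted p 0.00240), and Fosl1, Fosl2, Myc, Dusp1 and Klf6 differed 1 by 1.

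**Figure D2:**
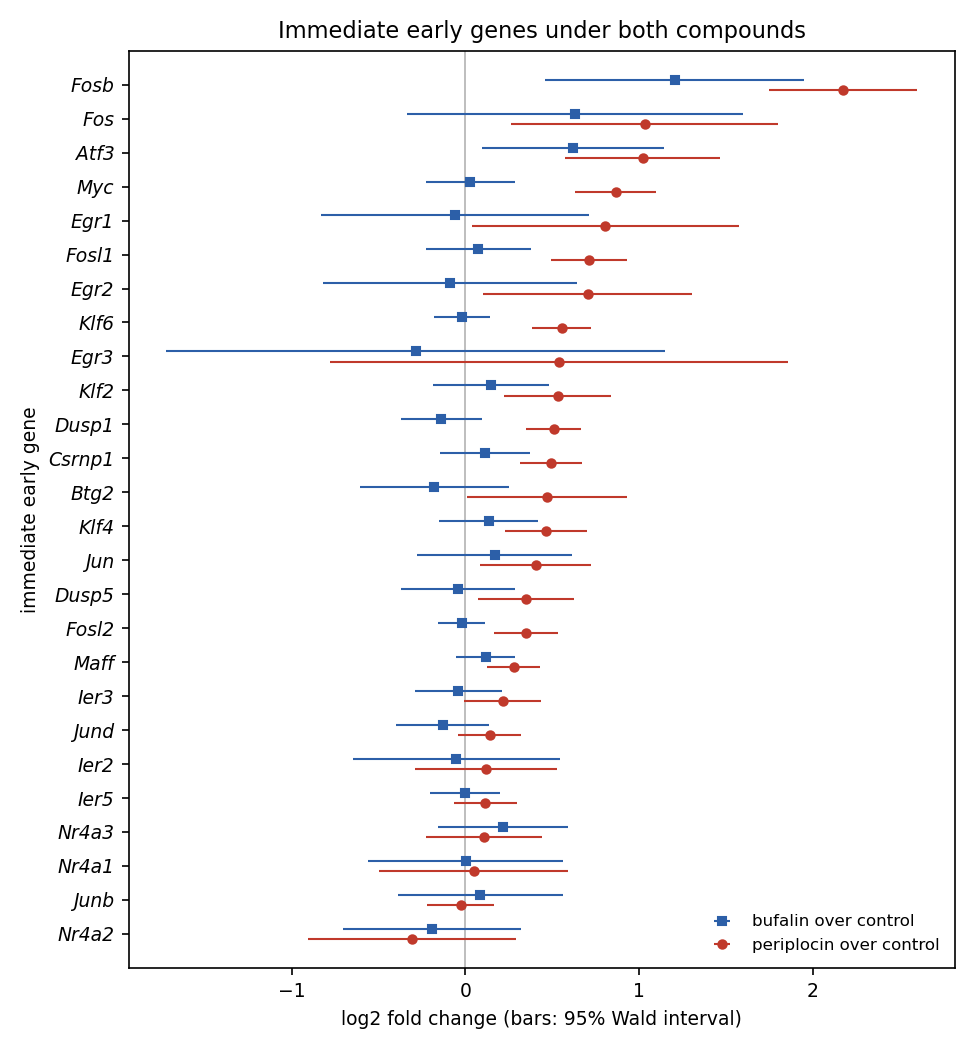
Log2 fold change over control of the 26 immediate early genes, with bufalin as blue squares and periplocin as red circles, and bars for the 95% Wald interval. The periplocin values lie above 0 for 24 genes, with a median of 0.47, and the bufalin values for 13, with a median of 0.00.

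Genes of the cell cycle and DNA replication had lower medians with both compounds, -0.12 with bufalin (39 of 45 below 0, adjusted p 0.00120) and -0.10 with periplocin (35 of 45 below 0, adjusted p 0.00167). No member was called, also with p re-adjusted over all genes that have one, which matters with bufalin, where only 10 of the 45 had an adjusted p. Adjusted over the list alone, 0 passed with bufalin, and with periplocin Ccna2, Top2a and Kif11 passed. Genes of glycolysis and the hypoxia response had higher medians, 0.19 with bufalin (23 of 26 above 0, adjusted p 0.00120) and 0.14 with periplocin (25 of 27 above 0, adjusted p 0.00167), again with 0 members called, over all genes or over the list alone. For neither list were the compounds shown to differ, with median differences of -0.00 (adjusted p 0.973) for the cell cycle and 0.05 (19 of 25 above 0, adjusted p 0.228) for glycolysis and hypoxia. These shifts were measured against 1 set of control libraries. Random lists treat genes as independent, so p-values of lists whose genes move together are too small.

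The remaining lists passed in the bufalin comparison and not in that of periplocin. Cholesterol synthesis and uptake had a median of -0.12 (20 of 24 below 0, adjusted p 0.00120), with 0 members called, and its compound difference was -0.09 (adjusted p 0.00240). The TGF-beta targets had a median of 0.16 (adjusted p 0.00120), opposite to their called members Ccn2 and Tgfb3, which fell. Adjusted over the list alone, 4 TGF-beta members rose and 3 fell: the inhibitory Smad7, Id2, Tgfbi and Ltbp2 were higher, and Ccn2, Tgfb3 and Tgfb2 lower. Myogenic and striated muscle genes had a median of 0.14 (adjusted p 0.0115) with Myh1 as the called member. Heat shock genes and chaperones stood at -0.06 (adjusted p 0.0304) and interferon-stimulated genes at -0.12 (adjusted p 0.0370), and neither passed with random lists matched on gene length as well, at adjusted p of 0.0713 and 0.0640. The natriuretic and cardiac stress list, with Ccn2 lower with bufalin, passed in the comparison of the compounds at -0.16 (adjusted p 0.0464). Over the TGF-beta targets the median difference between the compounds was 0.03 (adjusted p 0.655), but 4 of 14 members differed 1 by 1 and in both directions: Tgfbi (0.24, adjusted p 0.000248) and Ltbp2 (0.32, adjusted p 0.0115) were higher with bufalin, and Ccn2 and Tgfb3 lower. The compounds were not shown to differ over the muscle genes (-0.04, adjusted p 0.517), heat shock genes (-0.05, adjusted p 0.133) or interferon-stimulated genes (-0.05, adjusted p 0.405). With periplocin, cholesterol synthesis stood at -0.03, TGF-beta targets at 0.04, muscle genes at 0.05, heat shock genes at 0.01, with Hspb1 called, and interferon-stimulated genes at -0.07. The median of the cardiac stress list was -0.05 with bufalin and 0.10 with periplocin, and neither passed alone.

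Lists tied to the compounds' target and to the mark itself did not pass. Of 11 Na/K-ATPase subunits and regulators measured with bufalin only 3 had an adjusted p, and of 10 with periplocin all 10, and 0 of these were called. Re-adjusted over all genes with a p, 0 of the 11 passed, and 1 gene in each comparison had an unadjusted p under 0.05. That gene was Fxyd7 with bufalin, which passed when adjusted over the list alone, and Fxyd2 with periplocin, and both have RNA near the floor of detection. The list medians were 0.02 and -0.04. The beta subunits Atp1b1 and Atp1b3 were at -0.01 ± 0.06 (SE, log2) and 0.03 ± 0.08 with bufalin, and at 0.06 ± 0.06 and -0.03 ± 0.06 with periplocin, in the authors' deposited table. Of 22 m6A writers, erasers and readers 12 had an adjusted p with bufalin and 22 with periplocin, and 0 of these were called. Re-adjusted over all genes with a p, 0 of the 22 passed with bufalin, and 2 had an unadjusted p under 0.05 in each comparison; the list medians were 0.03 and -0.02. The methyltransferase Mettl3 was at 0.02 ± 0.08 and -0.04 ± 0.07, the demethylase Fto at 0.00 ± 0.08 and -0.05 ± 0.07, and the demethylase Alkbh5 at 0.33 ± 0.14 and -0.08 ± 0.12 with bufalin and periplocin in the authors' deposited table. Adjusted over the list alone, Ythdc1 (0.19 ± 0.07) and Hnrnpc (-0.15 ± 0.05) passed with periplocin in the authors' deposited table.

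With bufalin 17 of 24 tested lists did not pass, at adjusted p from 0.149 to 0.981, and with periplocin 22 of 25, at 0.190 to 0.921. Calcium handling stood at 0.01 and 0.01 (bufalin and periplocin medians), the integrated stress and unfolded protein response at 0.04 and -0.01, p53 targets at 0.02 and 0.05, apoptosis at -0.05 and -0.01, and ferroptosis and oxidative stress at 0.03 and 0.02. Extracellular matrix genes stood at 0.04 and -0.02, inflammation at 0.02 and 0.07, autophagy at 0.03 and 0.01, ribosomal proteins at 0.05 and 0.02, and nuclear-encoded oxidative phosphorylation at -0.04 and -0.02. Markers of other cell types were sparse: 3 of 10 endothelial, 3 of 12 leukocyte and 1 of 8 epithelial markers had a control mean of at least 10, the highest being Krt8 at 1057 normalized counts. Of smooth muscle markers 9 of 10 reached it, with medians of -0.03 and -0.02. Medians were -0.21 and -0.01 for the endothelial, -0.04 and 0.25 for the leukocyte and 2.06 with periplocin for the epithelial markers, of which only 4 were measured there and 2 with bufalin, too few for its test. The 13 transcripts of the mitochondrial genome were not listed in the tables.

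At the level of m6A, few peaks were called as changed, and how many true changes the authors' test would miss was not estimated. The deposited lists held 9866 peaks in 5122 genes for bufalin and 9170 peaks in 4879 genes for periplocin, with a median fold enrichment of IP over input of 1.82 and 1.81 and a median length of 150 bases in both. A positive change is read as a higher mark with the compound, but this direction is not stated. All peak values are the authors' own, and positions are on the rn6 build, counted from 1. Positions give the full span of a peak, which can join several blocks. The peaks called below held from 98 bases, for Zmynd19, to 250 bases, for Dock1.

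With bufalin, 3 peaks passed a false discovery rate (FDR) of 0.05 for the change in enrichment. In the authors' deposited table Smarcb1, a subunit of a chromatin remodeller, had a change of 4.89 (log2) at an FDR of 0.0138, on the unplaced contig Un_AABR07024104v1 from 33995 to 37990. Dock1, an activator of Rac, had a change of 1.37 at an FDR of 0.0309 on chromosome 1 from 207330475 to 207340222, in the authors' deposited table. Rere, a transcriptional corepressor, had a change of -1.27 at an FDR of 0.0339 on chromosome 5 from 167657722 to 167657822, in the authors' deposited table. RNA of these 3 genes was not called with bufalin, but Smarcb1, at 0.01 ± 0.09 (SE, log2), had no adjusted p there and could not be called. At an unadjusted p under 0.05 there were 300 peaks, or 3.04% of the list, and 224 of them, or 74.7% (exact binomial interval 69.3 to 79.5%), were below 0 (two-sided exact binomial test, p = 4.28e-18, against a share of 50%). Over all 9866 peaks the share below 0 was 54.8% and the median change -0.02. Peaks are not independent replicates in this test, and 3.04% is below the share that a p of 0.05 gives without any change.

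With periplocin, 4 peaks passed the same FDR. Zmynd19 had a change of -6.42 at an FDR of 0.000501 on chromosome 3 from 2159141 to 2160553, and Rufy2 a change of 5.71 at an FDR of 0.00603 on chromosome 20 from 27228161 to 27230626, in the authors' deposited table. Anp32a, a nuclear phosphoprotein, had a change of 1.10 at an FDR of 0.0437 on chromosome 8 from 67326718 to 67327020, in the authors' deposited table. The Dlg4 peak on chromosome 10 from 56627596 to 56636087 changed by 0.24 in the authors' deposited table with a p at the numerical floor of the list, which its small change does not match. RNA of these 4 genes was not called with periplocin. At an unadjusted p under 0.05 there were 309 peaks, and 174 of them, or 56.3% (exact binomial interval 50.6 to 61.9%), were below 0 (two-sided exact binomial test, p = 0.0305). Among these peaks with a small p, the share below 0 was 18.4 percentage points higher with bufalin than with periplocin (two-sided Fisher's exact test, p = 2.56e-06), while over all peaks of each list the shares were 54.8% and 52.3%. That p treats the peaks of both lists as independent, although the lists share control libraries. The 309 peaks were 3.37% of the periplocin list, also below the share that a p of 0.05 gives without any change.

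**Figure D3:**
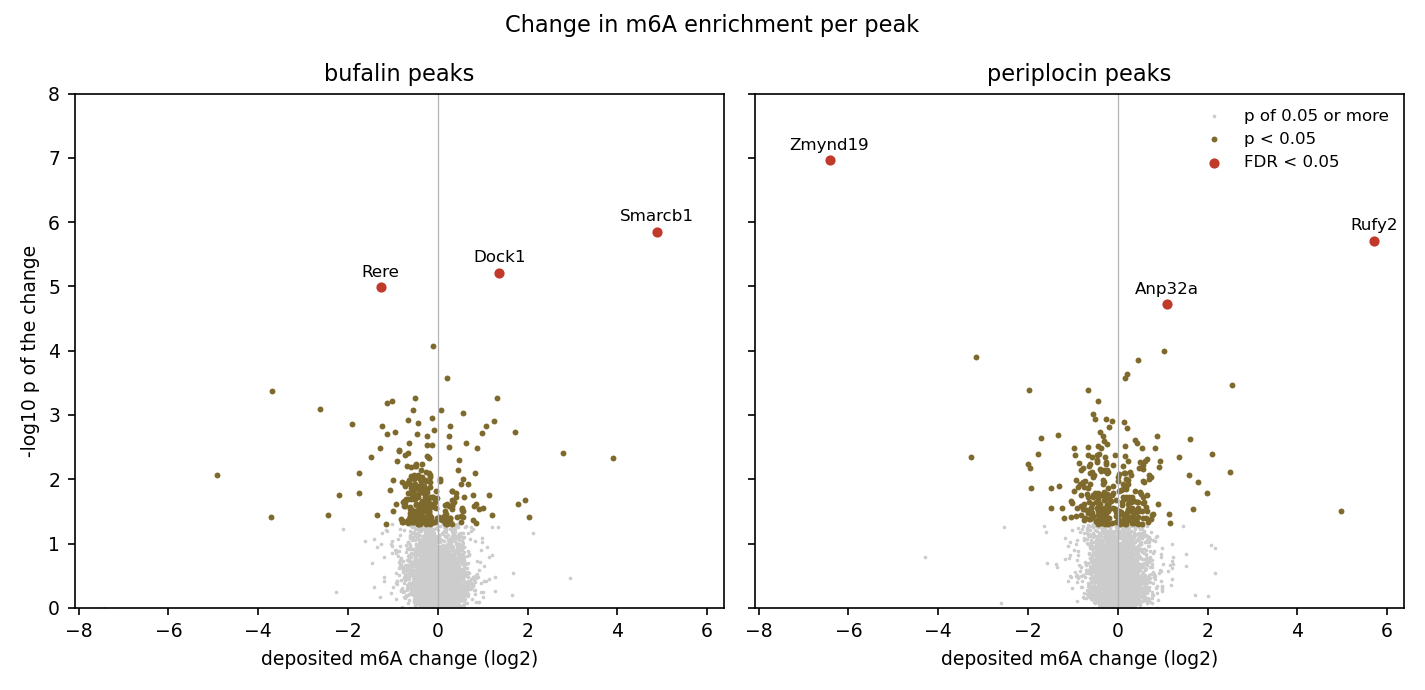
Deposited change in m6A enrichment (log2, horizontal axis) against the -log10 p of that change (vertical axis) for each peak of the bufalin list (left) and the periplocin list (right). Red points are the peaks past an FDR of 0.05, 3 with bufalin and 3 with periplocin beside the Dlg4 peak at the numerical floor, which is not drawn, and brown points are the other peaks past an unadjusted p of 0.05.

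None of the peaks past the FDR lay on a gene of the fixed lists. The m6A writers, erasers and readers carried 47 peaks on 16 genes with bufalin, with changes from -0.66 to 0.63, and 43 peaks on 17 genes with periplocin, with changes from -0.76 to 0.33, in the authors' deposited table. The immediate early genes carried 29 and 26 peaks, with medians of 0.01 and 0.05, and 1 and 0 of them passed an unadjusted p of 0.05. Na/K-ATPase genes carried 0 peaks with bufalin and 1 with periplocin, on Atp1b3, at -0.18 in the authors' deposited table.

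The peak lists of the compounds covered largely the same sites. Of the bufalin peaks, 8185 of 9866, or 83.0%, shared at least 1 base on the same strand with a periplocin peak, and of the periplocin peaks 8200 of 9170, or 89.4%. Shared bases were 72.6% of all bases in either list. Among 7627 peaks paired by an overlap of 50% of both, the changes correlated across peaks at a Spearman rho of 0.503, which includes what shared controls give. Both changes passed an unadjusted p of 0.05 at 57 pairs, where independent lists give 8.28, with 42 below 0 in both, 11 above 0 in both and 4 opposite (two-sided Fisher's exact test of direction, p = 7.40e-09). Hsp90aa1, the inducible HSP90 chaperone, chosen after the values were seen, had such a pair on chromosome 6 from 135110675 to 135111051, at -1.90 with bufalin and -1.98 with periplocin in the authors' deposited table. Dock1 was at 1.37 and 1.36 at its pair, and Rere at -1.27 and -0.68, in the authors' deposited table. The part that comes from the shared control libraries was not separated, because the lists hold no values per library.

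Changes in m6A and in RNA level were joined per gene. Across 5117 genes with a peak, the mean peak change and the log2 fold change of RNA with bufalin had a Spearman rho of -0.18 and a Pearson r of -0.09 (permutation p of 1e-05, the smallest that the permutations can give, and 8.70e-04, adjusted over 4 relations 2e-05 and 0.00116). With periplocin, across 4876 genes, rho was -0.09 (permutation p 1e-05, adjusted 2e-05) and r was -0.04 (permutation p 0.0162, adjusted 0.0162). For periplocin rho was -0.05 among genes with a mean count at or above the median and -0.12 with peaks of at least 2-fold enrichment, the latter setting chosen after seeing the data. The sign of these relations rests on the unstated direction of the m6A change, and read the other way each would be positive. Without the 2 genes farthest in m6A change r was -0.09 and -0.04. Genes are not independent replicates, and the input libraries may enter both readouts. All 10 bufalin genes and 49 of the 67 periplocin genes carried a peak. Of all tested genes with a mean of at least 200, 58.2% carried one with bufalin and 55.7% with periplocin. The called bufalin genes had higher means, of at least 2259. With only 3 and 4 called peaks, the absence of genes called in both carries no information. Of the called periplocin genes, Pik3c2a, Ahnak, Rnd3, Eea1, Plec, Tsc22d1, Acin1 and Arid4b, named after their values were seen, had a peak with an unadjusted p under 0.05, and of the bufalin genes 0 had one. A gene with many peaks, such as Ahnak with 25 in the periplocin list, has more chances of such a peak.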

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

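The 2 compounds differed in their change against control in 11 of the named genes, by the approximate Wald test of the difference. As bufalin minus periplocin on the log2 scale, the difference was 0.52 for H19, 0.70 for Myh1, -0.27 for Tgfb3, -0.30 for Ccn2, -0.84 for Myc, -0.99 for Vof16, -0.63 for Fosl1, -0.95 for Edn1, -0.64 for Ppp1r10, -0.59 for Plk3 and -0.31 for Thbs1. With the upper limit of the standard error only H19, Myh1, Myc, Vof16 and Edn1 of these still passed. By the same rule, the median difference was -0.087 for the cholesterol list and -0.16 for the natriuretic and cardiac stress list. Among m6A peaks past an unadjusted p of 0.05, the share with a negative deposited change was 18.4 percentage points larger with bufalin. Over all peaks the shares were 54.8% and 52.3%. The direction of that change is not stated, and read the other way this would be the share of higher peaks.

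Both tests of the next pattern were chosen after the result was seen. The immediate early genes also differed between the compounds, with a median of -0.38. Noise of the shared control libraries cancels arithmetically in this difference, so it was excluded as the whole cause; the list's p among random lists was 0.000200, which is too small where genes move together. For lower precision of the bufalin comparison, the interval of the difference included 0 for 10 of 26 members, and for 18 with the upper limit of the standard error. Myc, Dusp1 and Klf6 passed with either. Intervals of single genes do not test a shift of the whole list. In the difference 23 of 26 members were below 0, and median standard errors were 0.18 with bufalin and 0.15 with periplocin. Independent noise would scatter members to both sides, so these values argue against such noise as the cause of the list's shift. Lower precision from noise that moves the members together stays open. Noise shared by the treated libraries, and dose and time, were not tested, so a difference between the compounds as such is a hypothesis.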

How the results depend on the processing

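Of the results that answer a comparison, 30 values under alternative settings were labelled the same and 11 moved. Of single genes and lists, 83 were labelled the same and 9 weaker, and none reversed. For single genes these settings left the fold change itself untouched, and length matching left the list medians untouched. The absence of reversals therefore carries no information there. For counts of calls, the same meant close to the main value and not equal to it. For single genes and lists it meant that the adjusted p stayed under 0.05. Overlap shares and correlations followed other rules. Without the filter on low counts, bufalin calls went from 10 to 12 and genes between the compounds from 42 to 38. With length matching, bufalin lists went from 7 to 5. With a change of at least 1 on the log2 scale, 0 bufalin genes and 12 periplocin genes remained, and at an adjusted p of 0.01 there were 44 periplocin genes, 4 bufalin lists and 0 bufalin peaks; these stricter settings keep fewer by construction. The upper limit of the standard error left 8 genes between the compounds, and an unadjusted p under 0.05 in both tables gave 161 shared genes in place of 0; both settings were chosen after seeing the data. Adjusted over the list alone, 10 list members passed with bufalin and 33 with periplocin; this setting tests fewer genes and also drops the authors' filter on mean count, which alone, over all genes with a p, added 0 members. Overlap of peaks was 77.5% with a reciprocal overlap of 50% and 89.4% by gene, in place of 83.0%. With bufalin, the lists of heat shock and interferon genes no longer passed with length matching, nor did the interferon list with a mean of at least 10 (adjusted p 0.0542).

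No paired analysis was possible because the tables hold 1 value per gene and comparison. For the same reason, leaving out replicates, a replicate block, a fit of only the treated groups and other splits of the samples were not run. The relation of m6A and RNA among genes called in both at 0.01 has no value, as no gene was called in both. Precision limits detection: in simulated data, a best case with a known spread, 22% of changes of 0.25 on the log2 scale were found between the compounds.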

Other observations

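The tests of depth for the called genes, of the Mboat7 copies and of immunoprecipitation efficiency were chosen after the values were seen. The following genes passed with periplocin and were chosen after their values were seen, and no gene group is tested by them. In the authors' deposited table Hexim1, an inhibitor of transcription elongation, rose by 0.39 ± 0.08 (SE, log2), the chromatin reader Brd2 by 0.45 ± 0.09, the general transcription factor subunit Taf7 by 0.39 ± 0.09, the helicase Ddx5 by 0.17 ± 0.03 and the RNA-binding protein Hnrnpdl by 0.27 ± 0.05. Ppp1r15b, the constitutive relative of Ppp1r15a, rose by 0.26 ± 0.05 in the authors' deposited table. Further rises were those of the cytoskeletal linker Plec by 0.28 ± 0.05, Ahnak by 0.24 ± 0.04, Dst by 0.19 ± 0.04, Macf1 by 0.16 ± 0.03 and the dynein heavy chain Dync1h1 by 0.21 ± 0.04, in the authors' deposited table. None of these genes passed the test of the difference between the compounds.

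Some genes were near 0 in control and present after treatment, such as Mboat7. For the 8 called with periplocin, 1.11% of 1083 genes at their level with periplocin (interval 0.574 to 1.93%), or 12 genes, had a fitted mean under 0.3 in control. Depth in control thus did not hide most genes of that level. That level was set by the 8 called genes themselves, whose fitted control means lay under the same limit. The test therefore cannot exclude too little depth in control for these 8 genes. Over all genes, the criterion set beforehand for shallower control libraries was met. A fitted mean under 0.3 was found for 965 of 13239 genes in control, against 877 with bufalin and 854 with periplocin. The excess in control was 88 and 111 genes, past the limits of 85.8 and 85.3. Genes were lost after treatment (37 and 41) as well as gained (51 and 79). Shallower control libraries thus stay open as a part of the cause, and the size of that part was not measured. For Mboat7, reads moved from its copy Mboat7l1 were excluded as the whole cause, since the summed mean of both was higher by 1.11 with periplocin (interval 0.66 to 1.56, log2, with the copies taken as fully correlated). Mboat7 had a fitted mean of 61.3 with bufalin too, against 66.1 with periplocin, so its call with periplocin alone does not separate the compounds.

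Of the bufalin peaks past an unadjusted p of 0.05, 224 of 300 had a negative deposited change, against 54.8% of all bufalin peaks, and negative means a lower enrichment only if the change runs as treated over control. The negative share was 84.3% at an enrichment of 1 to 1.5 and 42.9% of 21 peaks at 3 or more, and with periplocin 65.9% and 36.8%. Against a lower efficiency of the bufalin immunoprecipitation, strong peaks did not fall most in that reading (rho of enrichment and change 0.0600, interval 0.0397 to 0.0805), but the direction is not stated, so this stays open. For a rise of the host gene's RNA in the input, 58.2% of 98 peaks on genes with an RNA fold change of 0 or below were negative (interval 47.8 to 68.1%), against 82.7% of the other 202. That split needs the same direction and RNA values from input libraries, which is not stated either, and shared input libraries would tie it to the change itself.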
